A study of Mus musculus with 8 samples.

How the data were processed

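Gene expression was measured by poly(A)-selected RNA sequencing of mouse blastocysts obtained by in vitro fertilisation of outbred ICR animals. There were 8 libraries, each from a pool of 5 embryos. In 4 libraries the embryos had been cultured in KSOM medium with a miR-21-5p agomir at 50 nM from fertilisation to the blastocyst stage. An agomir is a chemically modified double-stranded mimic of a microRNA. The other 4 libraries came from embryos cultured with vehicle and no oligonucleotide. The labels call the libraries of a group biological replicates from separate pools and put all 8 in a single batch. They do not say whether the pools came from separate fertilisation sessions or parents, so p-values measure the spread between these pools. No control with an unrelated oligonucleotide was part of the comparison. RNA was extracted with TRIzol and a glycogen carrier, and libraries were sequenced in paired ends, per the labels' protocols.

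The deposited table gave, per the file headers, a count and an FPKM value for 22013 genes with Ensembl identifiers in each library. Per the submitters' processing notes, the tools included fastp 0.18.0, FastQC, MultiQC, HISAT2 2.1.0, StringTie 1.3.1, RSEM and DESeq2 1.36.0, and the genome build was GRCm39. The role of each tool, the annotation release and the strand setting are not given in the sources used here. The deposited count columns were taken to be expected counts, the fractional counts of RSEM, since 1212 of their 176104 values were not whole numbers, and they were rounded before any count model. The deposited FPKM values, which are scaled by the authors to gene length and library total, were used only in an alternative test. Every per-sample column of the table belonged to 1 of the 8 libraries, and 0 columns belonged to other samples. Genes that share sequence with a close copy, such as the Hba-a1 gene or the ribosomal protein genes, can exchange reads in such counts, and overlapping antisense genes cannot be told apart without the strand setting. Small RNAs were not measured, so the level of miR-21-5p itself was not analysed here.

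Total counts ranged from 12246102 to 23147449 per library. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 12366 genes and removed 0.0862% of all counts. Groups were compared with edgeR 4.0.16 in R 4.3.3 (TMM scaling, robust quasi-likelihood fit, F test, no covariate), and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Expression levels are CPM, counts scaled to a common TMM-adjusted library total, given as mean ± SD over n = 4 libraries per group. Log2 fold changes are agomir over blank control, and p-values are 2-sided unless stated otherwise. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic, unless stated otherwise. On simulated counts with the means and library sizes of this comparison and 200 changed genes, the procedure recovered 22% of genes changed 2-fold among 12160 tested and 84% of genes changed 4-fold among 12161 tested. Among simulated genes with a mean of at least 5 CPM it recovered 30.3% of the 2-fold and 95.9% of the 4-fold changes. Of the simulated calls, 4.35% and 2.33% were false. Simulated genes were drawn independently and no library was made to stand apart, so these rates need not hold for the real libraries.

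Before the data were examined, 32 gene lists were fixed from textbook knowledge. The 28 lists with at least 5 measured genes were tested with camera of limma 3.58.1, which compares a list with all other genes, with its preset correlation of 0.01 between genes. Camera with an estimated correlation and fry, a rotation test of a list by itself, were run beside it. For the seed test, 3' untranslated regions were taken from GENCODE release M21 by Ensembl identifier. That release is built on GRCm38, not the build of the deposited table, so no coordinates were combined. The longest annotated 3' untranslated region of each gene was searched for the 7-base match ATAAGCT to the miR-21-5p seed, and 12222 of the 12366 tested genes (98.8%) had a region to search. The difference in mean log2 fold change between genes with and without the match was set against the same difference for 419 rearrangements of its bases. The separation of the groups was measured as the ratio of the mean distance between groups to the mean distance within groups (1 minus Pearson's correlation of log2 CPM), with an exact permutation test over the 35 splits of 8 libraries into 4 and 4.

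Named genes followed a rule fixed before the data were examined. Up to 12 genes per direction past the threshold, with at least 5 CPM and groups that do not overlap, would be named by size of change. From each list up to 4 measured members with the smallest p were eligible. Genes fixed by name, whatever their values, included Pdcd4, Spry1, Spry2, Reck, Tpm1, Btg2, Timp3, Smad7, Cdx2, Nanog, Pou5f1, Sox2, Gata6 and Sox17. Because fewer than 12 genes passed, the 6 genes with the smallest p in each direction and a mean of at least 5 CPM are given as values that did not pass in edgeR. Any other gene is said to be chosen after its values were seen.

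Alternatives covered scaling (DESeq2 median of ratios, upper quartile, library size), the test (DESeq2 1.42.0, limma-voom with sample quality weights, limma-trend on log2 FPKM plus 1 or 0.1 for genes with mean FPKM of at least 1), the filter (none, or 5 CPM in at least 4 libraries), the replicate number as a block, the summed expression of 4 Y-linked genes as a covariate, and each library left out in turn. Library pairs were also compared by chi-square on their counts. The smallest value per degree of freedom was 38.1, so no pair agreed within sampling noise. Figures and the seed test were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Xist was among the sex-linked genes listed but was not analysed here.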

Results

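The data comprised 8 poly(A) RNA libraries of pooled mouse blastocysts, 4 from embryos cultured with a miR-21-5p agomir at 50 nM and 4 from blank controls that received vehicle alone. Total counts were 12246102, 18983972, 21271696 and 20830135 in blank control libraries 1 to 4 and 19725944, 19246904, 18799156 and 23147449 in agomir libraries 1 to 4. A count was found for 15306 ± 467 genes (SD, n = 4) in controls and 14994 ± 364 genes (SD, n = 4) in agomir libraries, a difference within the spread between pools (exact permutation test, two-sided p = 0.286, where the smallest possible p is 0.0286). Mitochondrially encoded genes took 7.54% ± 0.576 of counts in controls and 7.32% ± 2.71 with the agomir (SD, n = 4; exact permutation p = 0.8286). Their share was 5.08% and 4.87% in agomir libraries 1 and 2, and 9.86% and 9.47% in agomir libraries 3 and 4. Control 2 lay apart from the other libraries on the first principal component (25.0% of variance) and agomir 3 on the second (21.9%).

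The first question was which genes of the blastocyst differed after culture with the miR-21-5p mimic. The smallest p-values belonged mostly to genes with lower expression in the agomir pools. Il10rb, a receptor chain of the interleukin-10 family, had 17.0 ± 16.1 CPM in controls and 0.318 ± 0.218 CPM with the agomir (log2 fold change -5.74, SE 0.90). Its control libraries ranged from 1.89 to 38.2 CPM. Kcnv2, a potassium channel subunit, had 9.40 ± 0.967 against 3.54 ± 0.524 CPM (log2 fold change -1.41, SE 0.24), and Me1, the cytosolic malic enzyme that makes NADPH, had 72.6 ± 9.03 against 39.6 ± 4.20 CPM (log2 fold change -0.87, SE 0.17). Mgarp, which encodes a mitochondrial protein, had 36.1 ± 8.62 against 14.5 ± 3.69 CPM. The insulin receptor adaptor gene Grb14 had 13.7 ± 4.89 against 4.20 ± 1.364 CPM, and the F-box gene Fbxl20 had 16.3 ± 2.07 against 8.07 ± 0.701 CPM. In the other direction, Kalrn had 3.15 ± 0.907 CPM in controls and 8.80 ± 3.22 CPM with the agomir (log2 fold change 1.48, SE 0.34), and the sphingosine 1-phosphate receptor gene S1pr1 had 7.23 ± 1.67 against 14.999 ± 3.30 CPM (log2 fold change 1.06, SE 0.25). Morc4 had 3.89 ± 0.850 against 8.38 ± 1.68 CPM, the centrosomal gene Cep70 had 33.8 ± 1.82 against 54.8 ± 11.5 CPM, the carbonic anhydrase gene Car2 had 10.1 ± 3.74 against 25.8 ± 11.6 CPM, and the transcription factor gene Mycn had 31.7 ± 15.9 against 70.4 ± 17.4 CPM. The 4 agomir libraries lay wholly on one side of the 4 controls for each of these 12 genes except Mycn.

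Of 12366 genes tested, 0 passed an FDR of 0.05 in edgeR's quasi-likelihood test, and the smallest FDR was 0.299. At an unadjusted p under 0.05 there were 789 genes, 326 higher and 463 lower, where 618.3 would be expected by chance. At p under 0.001 there were 25 genes, 24 of them lower, against 12.4 expected. The groups did not overlap for 481 genes, or 3.89% of those tested, where chance gives 2.86%. DESeq2 called 35 genes, 3 higher and 32 lower, of which 5 were removed by edgeR's filter and the other 30 had an unadjusted p under 0.05 in edgeR. They included 9 of the 12 genes named above, all but Cep70, Car2 and Mycn. limma-voom with quality weights and limma-trend on FPKM called 0 genes each. Without control 4, edgeR called 1 gene, Il10rb (log2 fold change -6.11, adjusted p = 0.0180). Without TMM scaling the median of all genes moved to -0.11 on the log2 scale, and 658 of 801 genes with p under 0.05 were then lower. With upper-quartile scaling, 613 of 816 were lower. Libraries of different groups were 1.07 times as far apart as libraries of one group (exact permutation test over 35 splits, one-sided p = 0.0571).

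**Figure D1:**
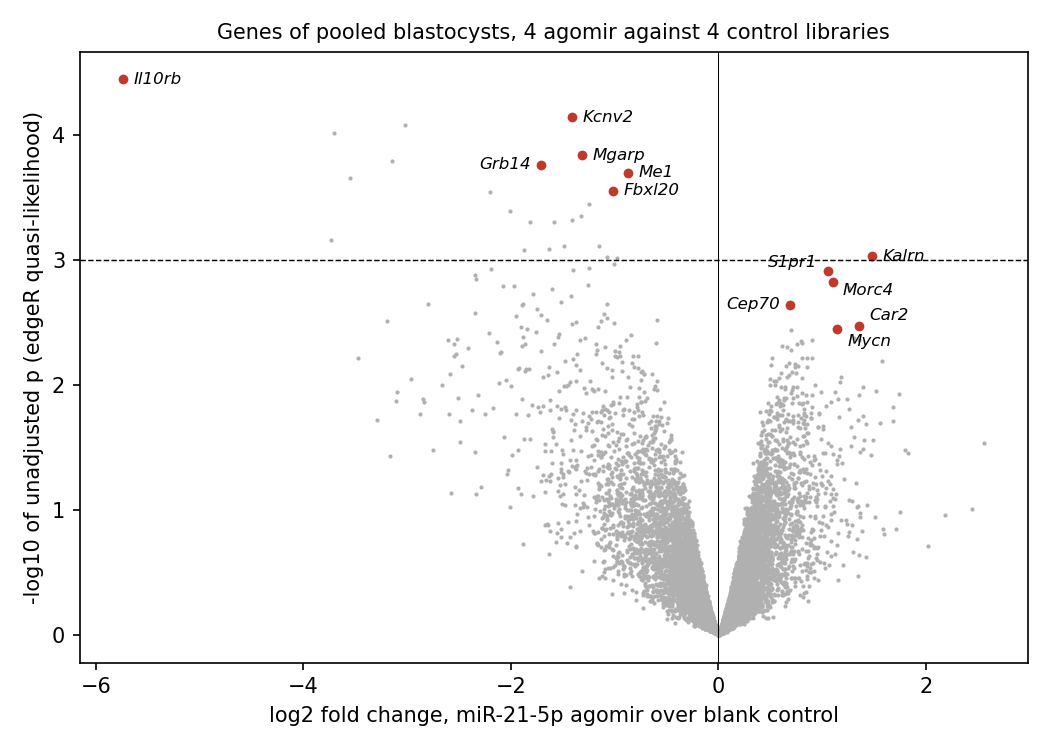
Each point is 1 of the 12366 genes tested, with the log2 fold change of agomir over blank control on the x axis and -log10 of the unadjusted p of edgeR's quasi-likelihood test on the y axis (4 libraries per group). Red points are the 12 named genes, of which 0 passed an FDR of 0.05 in edgeR and 9 did in DESeq2, and 24 of the 25 genes above the dashed line at 3 lie on the left.

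Reported targets of miR-21-5p were examined next, since a mimic would be expected to lower them. In this list 26 of 27 genes were measured, 16 with a higher and 10 with a lower mean in the agomir pools, and the list did not differ from other genes (median log2 fold change 0.15, camera FDR = 0.625, adjusted p = 0.856 with an estimated correlation). Pdcd4, a translation inhibitor often used as a readout of miR-21, had 111 ± 24.3 CPM in controls and 98.8 ± 33.7 CPM with the agomir (log2 fold change -0.17, SE 0.25, edgeR adjusted p = 0.927), and its fold change turned to 0.038 under limma-voom with quality weights. The antiproliferative gene Btg2 had 58.7 ± 24.8 against 54.4 ± 14.4 CPM. The receptor signalling inhibitors Spry1 and Spry2 had log2 fold changes of 0.25 (SE 0.38) and 0.23 (SE 0.33). For the protease inhibitors Timp3 and Reck they were 0.26 (SE 0.26) and -0.44 (SE 0.72), and Reck was at 1.42 ± 0.260 CPM in controls and 1.03 ± 0.692 CPM with the agomir. Reck was at -0.040 without agomir 3 and -0.68 without agomir 2, and Timp3 at 0.11 without control 1 and 0.49 without control 3. The tropomyosin gene Tpm1 had 266 ± 24.6 against 354 ± 125 CPM, with 540 CPM in agomir 3. The smallest p-values of the list were those of Sesn1, a stress-responsive gene, at 9.76 ± 1.54 against 6.41 ± 0.844 CPM (log2 fold change -0.60, SE 0.23, edgeR adjusted p = 0.691), and of Fasl, at 0.758 ± 0.415 against 1.86 ± 0.645 CPM (log2 fold change 1.27, SE 0.48), Smad7 (0.73, SE 0.32) and Pik3r1 (-0.52, SE 0.24). Smad7 was at 0.40 without agomir 2 and Pik3r1 at -0.28 without control 3. The groups were wholly apart for Sesn1, lower with the agomir, and for Fasl, higher with the agomir. Of these genes 0 passed an FDR of 0.05 adjusted over the list alone, and the smallest such FDR was 0.283. In the search for seed matches described next, Sesn1, Btg2 and Tpm1 held none. Fasl, Pdcd4, Spry1, Spry2, Reck, Timp3, Smad7 and Pik3r1 each held a match.

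**Figure D2:**
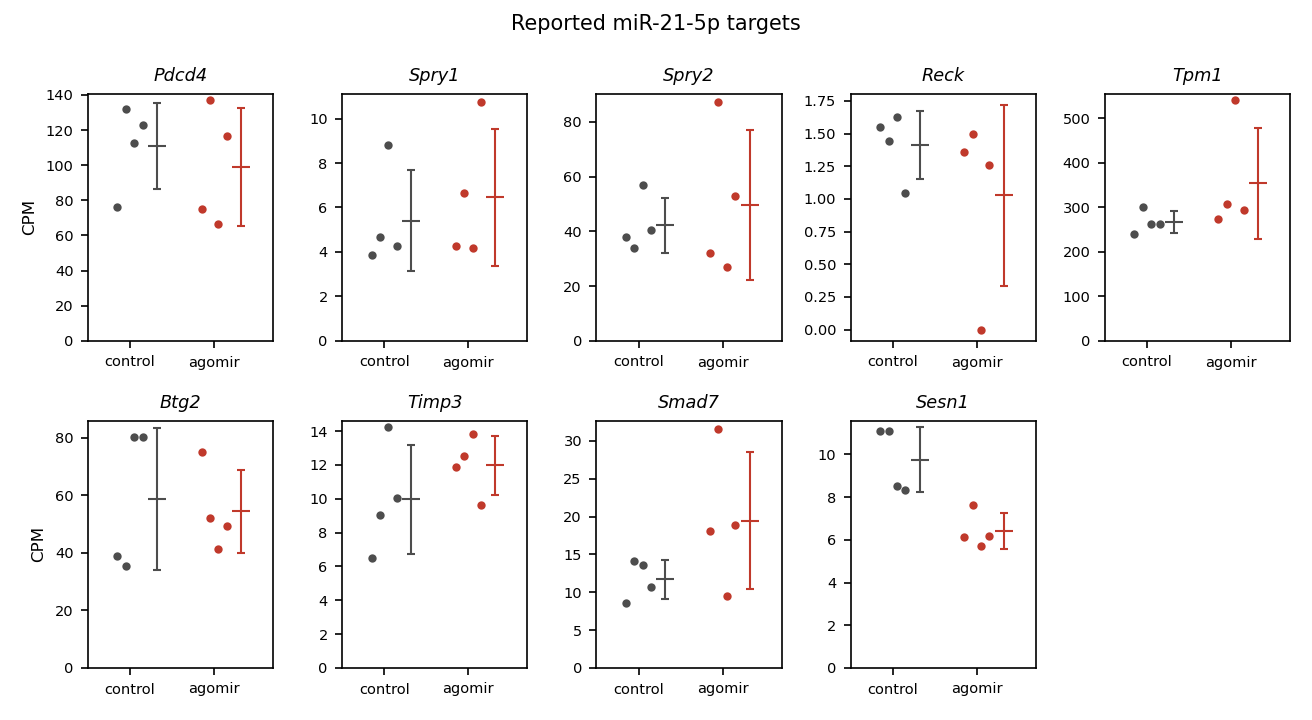
CPM of 9 reported miR-21-5p targets in each of the 4 blank control libraries (grey) and 4 agomir libraries (red), with the group mean and SD as a bar beside the points and a separate linear axis for each gene. The points of the groups overlap for each gene drawn except Sesn1, where the 4 agomir libraries lie between 5.69 and 7.63 CPM and the controls between 8.34 and 11.1 CPM.

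A test that does not depend on published targets used matches to the miR-21-5p seed. Among 12222 genes with an annotated 3' untranslated region, 961 held at least one match and 11261 held none. Mean log2 fold changes were -0.055 with and -0.036 without a match, a difference of -0.018 (SE 0.014 across genes, which are not independent replicates). The 419 rearrangements of the same 7 bases gave a median difference of -0.030, and the central 95% of them lay between -0.064 and 0.0091, so the seed match stood inside that range (permutation of the bases, two-sided p = 0.443). Camera gave p = 0.489 for the genes with a match, and p = 0.533 with an estimated correlation. Without agomir 3 the difference turned to 0.0096. Regions with a match were longer (median 2750 bases) than those without (1029 bases), and with length and mean expression in a linear model the difference was -0.0013.

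The first lineage decision of the embryo separates trophectoderm, the outer layer that forms the placenta, from the inner cell mass. Trophectoderm genes stood higher in the agomir pools: 17 of 19 measured members had a higher mean, and the list exceeded other genes by 0.52 on the log2 scale (camera FDR = 2.7e-06, adjusted p = 0.289 with an estimated correlation). The transcription factor gene Gata3 had 135 ± 20.5 CPM in controls and 215 ± 76.8 CPM with the agomir (log2 fold change 0.68, SE 0.24), and Tfap2c had 25.0 ± 3.72 against 37.5 ± 9.82 CPM (0.59, SE 0.22). Tfap2a had a log2 fold change of 0.46 (SE 0.18), and Cdx2, the master regulator of trophectoderm, had 46.4 ± 18.9 against 63.3 ± 29.7 CPM (0.45, SE 0.33). The Cdx2 value was 0.078 without agomir 3 and 0.78 without control 2, and the Gata3 value was 0.45 without agomir 2. The keratin gene Krt7 had a log2 fold change of 1.39 (SE 0.51), of which 0.43 was left without agomir 3, a library with 70.6 CPM of Krt7. The excess of the trophectoderm list was 0.31 without agomir 3 (FDR = 0.000734) and 0.29 without both control 2 and agomir 3 (FDR = 0.000324), a pair left out after seeing the data. Averaged over the list, library means relative to the mean of all 8 libraries were -0.65, -0.35, 0.066 and -0.060 in controls 1 to 4. In agomir libraries 1 to 4 they were 0.13, 0.11, 0.76 and 0.00071, so agomir 4 lay below control 3. Genes of tight junctions and fluid transport, by which the trophectoderm fills the blastocoel, had 13 of 18 members higher and an excess of 0.30 (camera FDR = 0.0178, adjusted p = 0.444 with an estimated correlation). Among them Cldn4 had 343 ± 107 against 878 ± 497 CPM (log2 fold change 1.35, SE 0.39), Cldn7 159 ± 65.5 against 298 ± 99.1 CPM, and Cgn and the sodium pump subunit gene Atp1b1 had log2 fold changes of 0.70 (SE 0.27) and 0.40 (SE 0.16). This call was lost without control 1 (FDR = 0.0915) or without agomir 3 (FDR = 0.0561). The junction list averaged 0.30, 0.028, 0.31 and -0.11 in agomir libraries 1 to 4. In controls 1 to 4 it averaged -0.41, 0.084, -0.094 and -0.10.

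Inner cell mass and epiblast genes moved both ways, with 8 of 18 higher and 10 lower (camera FDR = 0.485). Pluripotency factor Nanog had 148 ± 57.7 CPM in controls and 102 ± 40.8 CPM with the agomir (log2 fold change -0.54, SE 0.31, edgeR adjusted p = 0.810), which was -0.30 without control 4 and -0.85 without agomir 4. Pou5f1 had 38.2 ± 27.2 against 26.2 ± 11.9 CPM, and Sox2 had 5.20 ± 1.14 against 4.14 ± 0.188 CPM. Klf4 had a log2 fold change of -0.77 (SE 0.23), Spic of -1.17 (SE 0.47) and Sall4 of 0.84 (SE 0.28). Without control 4 the Spic value was -0.77. Primitive endoderm genes, of the layer that forms the yolk sac, had 10 of 18 members higher (camera FDR = 0.531). Gata6 had 80.2 ± 15.7 against 79.0 ± 11.6 CPM and Sox17 had 12.6 ± 3.79 against 13.5 ± 3.12 CPM, differences whose sign depended on the processing. Hnf4a and Sox7 had log2 fold changes of -1.12 (SE 0.40) and 0.61 (SE 0.29).

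**Figure D3:**
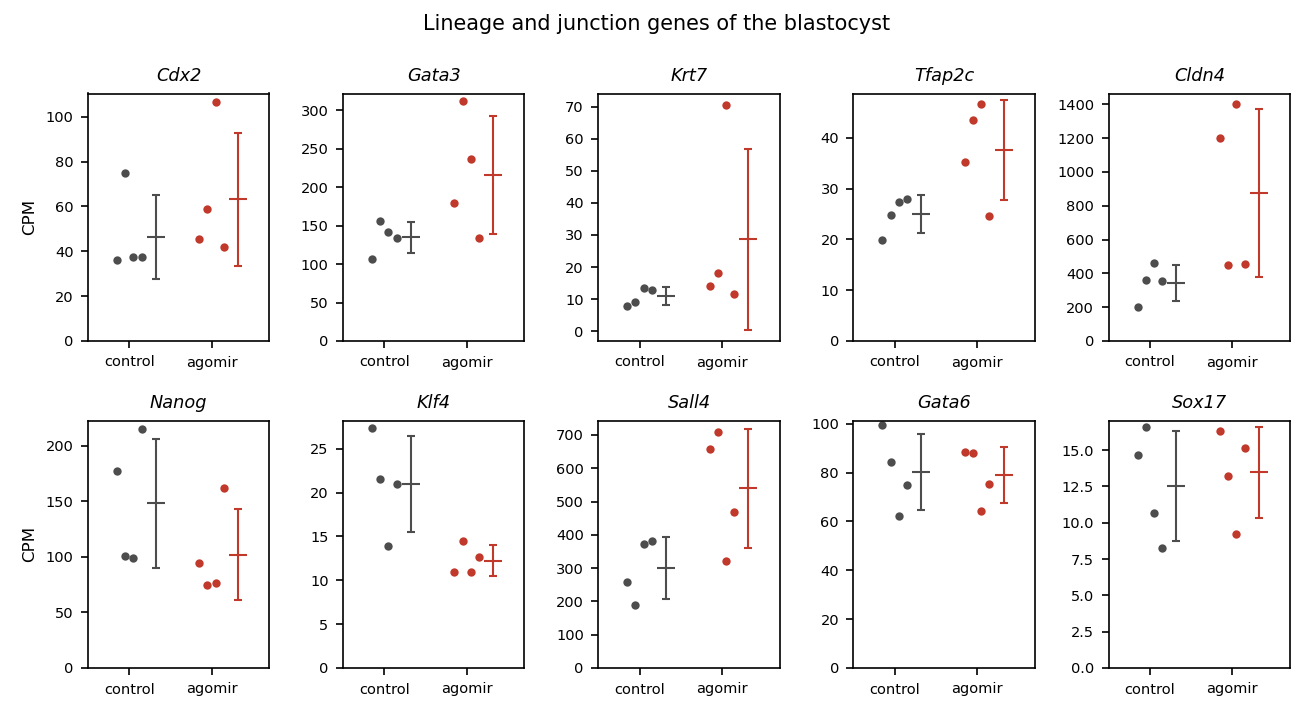
CPM of 10 lineage and junction genes in each of the 4 blank control libraries (grey) and 4 agomir libraries (red), with the group mean and SD as a bar beside the points and a separate linear axis for each gene. Agomir 3 is the highest library for Cdx2, Tfap2c, Cldn4 and Krt7, the last at 70.6 CPM where the next library has 18.0 CPM, and 0 of the 10 genes passed an FDR of 0.05 in edgeR.

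Of the other lists, 4 more stood higher in the agomir pools with the preset correlation. Nuclear-encoded subunits of oxidative phosphorylation had 64 of 74 members higher and an excess of 0.23 (camera FDR = 8.65e-05, adjusted p = 0.520 with an estimated correlation). Uqcrq had 759 ± 151 against 1092 ± 270 CPM, Atp5mc1 2443 ± 543 against 3364 ± 421 CPM, and Ndufa12 302 ± 56.6 against 401 ± 47.5 CPM. This list averaged 0.35 and 0.29 in agomir libraries 3 and 4 and -0.15 and -0.16 in agomir libraries 1 and 2, and its call was lost without agomir 3 (FDR = 0.0561) and without both control 2 and agomir 3 (excess 0.13, FDR = 0.0794). The share of mitochondrially encoded counts split the agomir libraries the same way. Imprinted genes had 12 of 17 members higher (excess 0.30, FDR = 0.0184, adjusted p = 0.328 with an estimated correlation), among them Mest with 6.54 ± 1.82 against 11.1 ± 2.65 CPM, Grb10 with 8.06 ± 3.20 against 15.1 ± 4.76 CPM and Peg10 with 1.85 ± 1.20 against 5.10 ± 3.86 CPM, and the call was lost without control 4 (FDR = 0.0623). Control 3 averaged 0.25 over the imprinted list, above the agomir libraries at 0.11 to 0.20. The other controls lay between -0.41 and -0.24. Cell cycle genes had 25 of 35 higher (excess 0.17, FDR = 0.0277, adjusted p = 0.436 with an estimated correlation), with log2 fold changes of 0.59 (SE 0.25) for the replication licensing gene Cdc6 and 0.41 (SE 0.20) for Rrm2, which were 0.29 and 0.27 without agomir 3. Cholesterol synthesis genes had 15 of 20 higher (excess 0.27, FDR = 0.0355, adjusted p = 0.520 with an estimated correlation), with 64.4 ± 12.8 against 100.03 ± 26.0 CPM for Hmgcs1 and a log2 fold change of 0.79 (SE 0.33) for Mvd, which was 0.45 without agomir 3. Without agomir 3 the excess was 0.052 for the cell cycle (FDR = 0.147) and 0.14 for cholesterol synthesis (FDR = 0.335). The cell cycle call was also lost without control 3 (excess 0.11, FDR = 0.241), control 4 (0.076, FDR = 0.0646) or agomir 2 (0.041, FDR = 0.149), and the cholesterol call without control 1 (FDR = 0.0915), control 4 (FDR = 0.0762) or agomir 4 (FDR = 0.0832). Without both control 2 and agomir 3 the cholesterol call was lost too (excess 0.14, FDR = 0.169). Library-size scaling (FDR = 0.0668) and FPKM (FDR = 0.142 and 0.144 with pseudocounts of 1 and 0.1) ended the cell cycle call, and a filter at 5 CPM (FDR = 0.0655) the cholesterol call. With no filter the excess was 0.44 for oxidative phosphorylation, 0.44 for cholesterol synthesis and 0.48 for the junction list. With FPKM it was 0.12 and 0.15 for oxidative phosphorylation, and 0.47 for imprinted genes with a pseudocount of 0.1.

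Another 2 lists stood lower. Genes linked to implantation competence had 10 of 11 measured members lower, at -0.29 relative to other genes (camera FDR = 0.0153, adjusted p = 0.289 with an estimated correlation), and this call held without each library in turn. With no filter on low counts the list stood at -0.70. The integrin gene Itgav had 19.1 ± 3.17 against 14.2 ± 2.35 CPM, the cathepsin gene Ctsl had 360 ± 74.4 against 285 ± 68.4 CPM, and the growth factor receptor gene Egfr was near 1 CPM in controls (log2 fold change -1.08, SE 0.69). Autophagy and lysosome genes had 14 of 20 members lower, at -0.16 relative to other genes (camera FDR = 0.0355, adjusted p = 0.289 with an estimated correlation). Gabarapl1 had 7.48 ± 0.981 against 3.46 ± 1.80 CPM, the autophagosome gene Map1lc3a 52.4 ± 19.3 against 25.8 ± 13.3 CPM, the cargo receptor gene Sqstm1 73.5 ± 40.4 against 39.1 ± 20.96 CPM, and the initiating kinase gene Ulk1 60.1 ± 13.5 against 39.2 ± 14.0 CPM. The log2 fold change of Sqstm1 went from -0.91 to -0.46 without control 2, and that of Ulk1 from -0.62 to -0.39 without agomir 3. The autophagy call was lost without control 3 (FDR = 0.0711), control 4 (FDR = 0.0884), agomir 2 (FDR = 0.142) or agomir 3 (FDR = 0.0607), and with no filter on low counts the list stood at 0.017. Without control 2 it passed at -0.096. In all, 8 of 28 lists passed camera's threshold with the preset correlation, 0 with an estimated correlation (smallest FDR 0.289) and 0 in fry's directional test (smallest FDR 0.148).

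**Figure D4:**
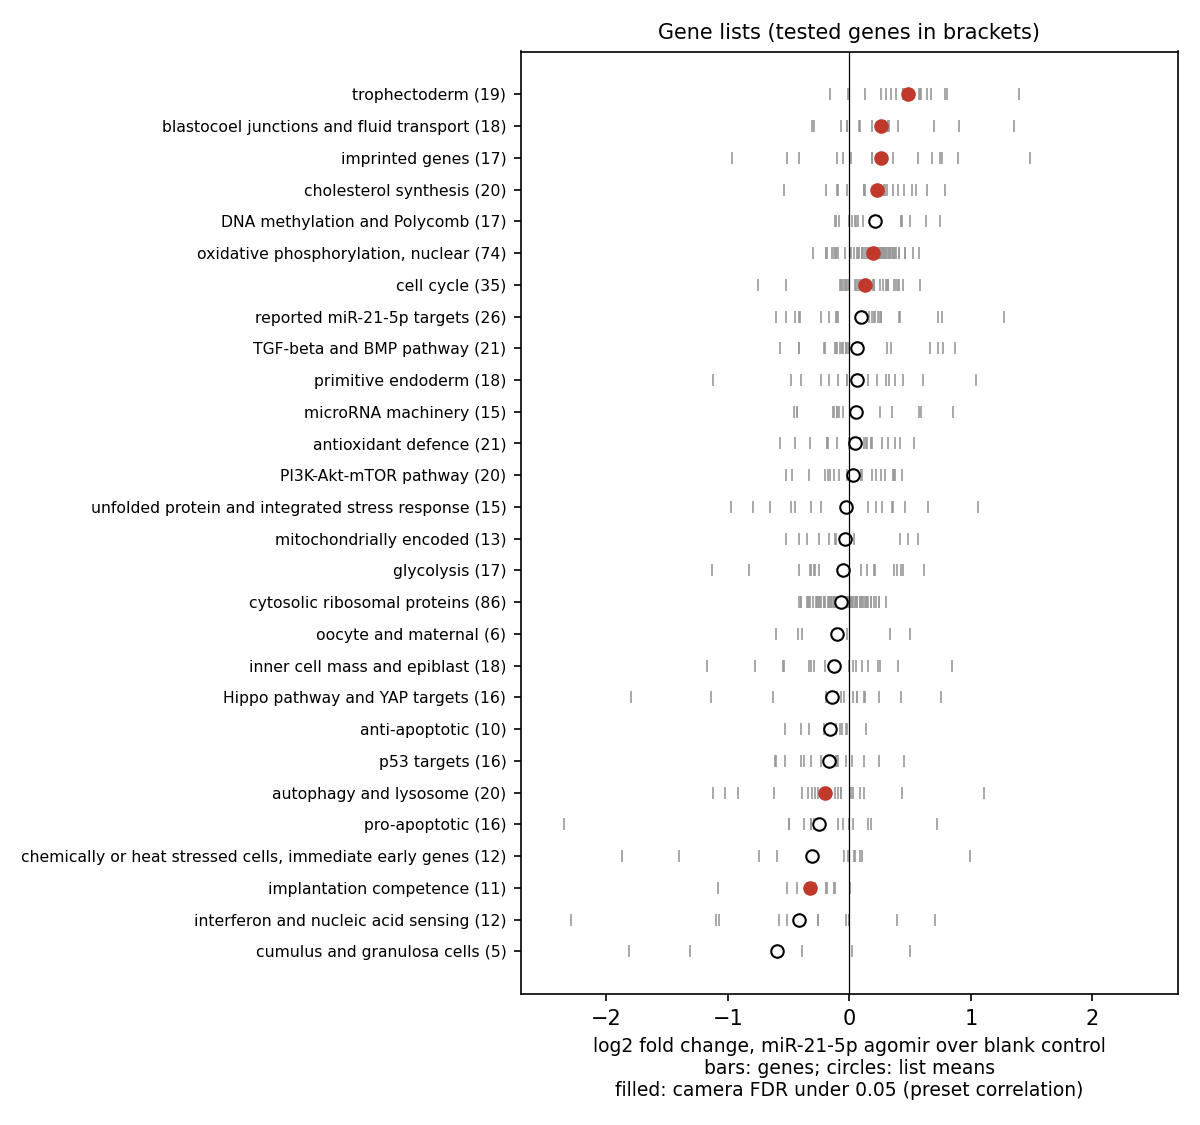
Log2 fold change of agomir over blank control for the measured genes (grey bars) and mean (circle) of each of the 28 lists tested, ordered by the mean relative to other genes, with the number of genes in brackets. Filled circles are the 8 lists past FDR 0.05 in camera with its preset correlation, 6 to the right of 0 and 2 to the left, and 0 lists passed with an estimated correlation.

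The remaining lists did not pass in the comparison as planned, and several passed under other processing or without a single library, each time with the preset correlation. Closest to the threshold were DNA methylation and Polycomb genes, with 13 of 17 higher (FDR = 0.0516, adjusted p = 0.520 with an estimated correlation), including the de novo methyltransferase genes Dnmt3a (log2 fold change 0.50, SE 0.18) and Dnmt3b (0.44, SE 0.17). This list passed without control 1 (FDR = 0.0363), control 2 (FDR = 0.0401), agomir 1 (FDR = 0.0371), agomir 3 (FDR = 0.0130) or agomir 4 (FDR = 0.0290). It did not pass without control 3, control 4 or agomir 2. Relative to all 8 libraries, the list averaged 0.40 in agomir 2 and 0.025, -0.041 and -0.034 in agomir libraries 1, 3 and 4. Its averages in the controls lay between -0.13 and -0.044. With all libraries it passed with DESeq2 size factors (FDR = 0.0416), limma-voom (FDR = 0.0298), no filter (FDR = 0.0139) and the Y-linked covariate (FDR = 0.0463). Interferon and nucleic acid sensing genes had 10 of 12 lower (FDR = 0.0646, adjusted p = 0.328 with an estimated correlation), and Bst2, with 18.4 ± 4.54 against 8.73 ± 1.67 CPM, was the 1 member to pass adjusted over the list alone (FDR = 0.0114). Over all genes it did not pass in edgeR (0 genes did) and passed in DESeq2 (adjusted p = 0.0386). The interferon list passed without control 2 (FDR = 0.0401), with limma-voom (FDR = 0.0430), no filter (FDR = 0.0127) and the Y-linked covariate (FDR = 0.0463). Genes regulated by p53 had 12 of 16 lower (FDR = 0.0692, adjusted p = 0.520 with an estimated correlation), with Cdkn1a at 42.5 ± 8.57 against 27.8 ± 4.67 CPM, and passed without control 2 (FDR = 0.0137) or agomir 1 (FDR = 0.0220). With all libraries the p53 list passed with limma-voom (FDR = 0.0154), the filter at 5 CPM (FDR = 0.0209) and FPKM plus 1 or 0.1 (FDR = 0.0406 and 0.0390). Pro-apoptotic genes had 12 of 16 lower (FDR = 0.103, adjusted p = 0.328 with an estimated correlation), and Bmf, at 1.14 ± 0.406 against 0.221 ± 0.118 CPM, was the 1 member to pass adjusted over the list alone (FDR = 0.0429) and did not pass over all genes. The pro-apoptotic list passed without control 2 (FDR = 0.0354) or agomir 4 (FDR = 0.0415), and with limma-voom (FDR = 0.0430). Anti-apoptotic genes had 9 of 10 lower (FDR = 0.211). Cytosolic ribosomal protein genes had 58 of 86 lower (FDR = 0.0705, adjusted p = 0.911 with an estimated correlation), at -0.029 relative to other genes, and passed without control 3 (-0.12, FDR = 0.00249), agomir 3 (-0.10, FDR = 0.000481) or agomir 4 (-0.095, FDR = 0.00235). With all libraries the ribosomal list passed with upper-quartile scaling (FDR = 0.0312), library size (FDR = 0.00128), limma-voom (FDR = 0.00397), the filter at 5 CPM (FDR = 0.00538), the Y-linked covariate (FDR = 0.0463) and FPKM plus 1 or 0.1 (FDR = 0.000282 and 0.000214). The estimated correlation between its genes was 0.531.

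Stress and immediate early genes had 7 of 12 lower (FDR = 0.116), among them Gadd45a (log2 fold change -1.40, SE 0.51). Mitochondrially encoded genes, with an estimated correlation of 0.653 between them, had 9 of 13 lower (FDR = 0.133, adjusted p = 0.856 with an estimated correlation), with a median of -0.11, a downward direction in camera and a mean of 0.0025 relative to other genes. They passed the threshold as lower without agomir 3 (-0.17, FDR = 0.0105) or agomir 4 (-0.16, FDR = 0.0080), under limma-voom (-0.22, FDR = 0.0180), with FPKM plus 1 (-0.18, FDR = 0.0434) or 0.1 (-0.16, FDR = 0.0390), and without both control 2 and agomir 3 (-0.20, FDR = 0.00299). mt-Nd6 had 260 ± 62.3 against 182 ± 38.5 CPM and mt-Cytb had 8092 ± 2860 against 11989 ± 5356 CPM. FDR was 0.560 for antioxidant defence, 0.811 for the Hippo pathway and YAP targets, 0.811 for the PI3K-Akt-mTOR pathway, 0.834 for microRNA machinery, 0.876 for the unfolded protein and integrated stress response, 0.876 for the TGF-beta and BMP pathway, and 0.948 for glycolysis. Medians and means relative to other genes differed in sign for the microRNA and TGF-beta lists, with medians of -0.085 and -0.049 and means of 0.091 and 0.11. The stress response and glycolysis lists had medians of 0.15 and 0.095 and means relative to other genes of 0.015 and -0.015, and camera gave both a downward direction. The Hippo list had a median of -0.0075. Single members with small p-values included Calr (log2 fold change -0.65, SE 0.24), Axl (-1.79, SE 0.63), Lin28a (0.85, SE 0.26), Tgfbr1 (-0.57, SE 0.21), Ldha (-0.82, SE 0.25) and Hk2 (0.62, SE 0.24).

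Markers of other cells that a pool could carry were measured in the same way. Of 16 cumulus and granulosa cell genes, the somatic cells that surround the oocyte, 5 passed the expression filter and 3 of these had a lower mean in the agomir pools, at -0.56 relative to other genes (camera FDR = 0.0692, adjusted p = 0.328 with an estimated correlation). The list passed without agomir 1 (-1.45, FDR = 0.0058), agomir 2 (-1.29, FDR = 0.00882), control 2 (-0.79, FDR = 0.0354) or control 4 (-0.96, FDR = 0.0268), and under limma-voom (-0.96, FDR = 0.0430), with no filter (-0.93, FDR = 0.0468) or with the Y-linked covariate (-0.54, FDR = 0.0463). Cyp11a1, the first enzyme of steroid synthesis, had 37.0 ± 16.7 CPM in controls and 10.5 ± 4.82 CPM with the agomir (log2 fold change -1.81, SE 0.38) and was the 1 gene of the list to pass adjusted over the list alone (FDR = 0.00248), with FDR = 0.362 over all genes in edgeR and an adjusted p of 0.00312 in DESeq2. Inha had 7.38 ± 4.39 against 2.97 ± 5.55 CPM, and agomir 1 held 11.3 of it where the other agomir libraries had at most 0.483 CPM. Star and Lum had means below 2 CPM in both groups. Of the maternal and oocyte genes 6 were measured (FDR = 0.876), with Dppa3 at 1753 ± 690 against 1152 ± 155 CPM. The 2-cell stage list had 3 measured genes and the blood list 2, too few for a test, all 5 with a lower mean in the agomir pools, and 0 of 8 sperm genes passed the filter. The 4 Y-linked genes measured, each with a lower mean in the agomir pools, summed to 123 ± 82.6 CPM in controls and 113 ± 41.3 CPM with the agomir (SD, n = 4; exact permutation two-sided p = 0.80), with 2.38 CPM in control 4 and between 57.3 and 184 CPM in the other libraries.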

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

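The test of extreme libraries was set before the data were examined, and the genes it ran on are those named in the text. In 12 cases of 166 groups of 4 values, the highest or lowest library lay further from the rest than Dixon's 95% limit, where chance at 1 in 20 would give 8.3. Control 2 and agomir 3, the libraries that lay apart on the principal components, held 4 of these cases each. Control 2 had 4.50 CPM of Car2 where the other controls had 11.7 to 12.2 CPM, and 74.7 CPM of the trophectoderm gene Cdx2 where they had 36.0 to 37.6 CPM. It also had 135 CPM of Atp1b1 (others 111.0 to 113.5 CPM) and 51.5 CPM of Cdc6 (others 33.3 to 35.1 CPM).

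Agomir 3 had 70.6 CPM of the keratin gene Krt7 against 11.6 to 18.0 CPM in the other agomir libraries, 540 CPM of Tpm1 against 274 to 307 CPM, 90.9 CPM of Cdc6 against 44.5 to 49.7 CPM, and 0 CPM of Reck against 1.26 to 1.498 CPM. Agomir 1 had 11.3 CPM of Inha against 0 to 0.483 CPM, and 4.42 CPM of Sox2 against 4.01 to 4.07 CPM. Spry1 stood at 8.79 CPM in control 3 against 3.88 to 4.69 CPM in the other controls, and Dppa3 at 1381 CPM in agomir 4 against 1052 to 1105 CPM in the other agomir libraries.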

How the results depend on the processing

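The choice of alternatives was made before the data were examined, except for leaving out control 2 and agomir 3 together and dropping control 7-mers with CG, which were chosen after seeing the data. The count of 0 changed genes held in each alternative except DESeq2's own test, with 35 genes (3 higher, 32 lower), and without single libraries it ranged from 0 to 1 in all, 0 to 0 higher and 0 to 1 lower, the 1 coming without control 4. Gene lists past the threshold numbered 15 with limma-voom, 13 without control 2 and agomir 3, 0 with an estimated correlation, 0 in fry, and 5 (without control 4) to 13 (without control 2) without single libraries. Of lists not past the threshold with all libraries, those for DNA methylation, interferon, cumulus cells, p53, ribosomal proteins, pro-apoptotic and mitochondrially encoded genes passed in at least 1 alternative with the preset correlation, and primitive endoderm without control 2 and agomir 3 (0.22, FDR = 0.0327). The separation of the groups was 1.15 (exact permutation p = 0.0286, the smallest possible) over the 500 most variable genes, and p ranged from 0.0286 to 0.457 over its alternatives. The reported targets stayed on the same side of the threshold throughout, from 0.0073 to 0.33 relative to other genes. The seed-match difference ranged from -0.041 to 0.0096 without single libraries, positive without agomir 3, and was 0.0070 without control 2 and agomir 3; the cause was not tested. With the replicate number as a block, 0 genes and 8 lists passed, and it changed no call of a gene. Same-numbered libraries correlated at -0.067, -0.057, -0.14 and 0.12, and 1 of 4 pairs was best with its own number, so the numbers were not taken as pairs. Depth limits the genes near 1 CPM, such as Reck, Bmf and Star.

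The following values turned in sign, and the cause was not tested. Mitochondrially encoded genes went to -0.0024 (upper quartile), -0.041 (library size), -0.22 (limma-voom), -0.078 (5 CPM filter), -0.11 (replicate block), -0.023 (Y-linked covariate), -0.18 and -0.16 (FPKM plus 1 and 0.1) and -0.20 (without control 2 and agomir 3). Glycolysis went to 0.088 (limma-voom), 0.082 (no filter), 0.012 (block), 0.0091 and 0.033 (FPKM) and 0.082 (without both libraries). The Hippo list went to 0.0027 (no filter), 0.0077 (5 CPM filter), 0.038 and 0.055 (FPKM), and the PI3K list to -0.027 (5 CPM filter), -0.010 and -0.025 (FPKM). With no filter the inner cell mass list was at 0.16, the pro-apoptotic list at 0.00097, ribosomal proteins at 0.15 and autophagy at 0.017. With the 5 CPM filter antioxidant defence was at -0.0093 and the TGF-beta list at -0.047. The oocyte list was at 0.0012 (block) and 0.013 (FPKM plus 0.1), the unfolded protein list at -0.028 (Y-linked covariate) and -0.20 (without both libraries), and the inner cell mass list at 0.0093 (without both libraries). Among genes, Sox17 was at -0.020 (library size), Gata6 at 0.0052 (DESeq2) and 0.094 (without both libraries), Pdcd4 at 0.038 (limma-voom) and 0.077 (without both libraries), and Spry2 at -0.00084 and -0.0076 (FPKM).

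Leaving out a single library turned or moved the fold change by over 1.5 times for 32 of the 78 named genes. Without single libraries the ranges that crossed 0 were -0.30 to 0.086 for Btg2, -0.12 to 0.10 for Gata6, -0.90 to 0.040 for Pou5f1, -0.052 to 0.27 for Sox17, -0.096 to 0.60 for Spry1 and -0.18 to 0.44 for Spry2. For lists they were -0.17 to 0.00030 (Hippo), -0.12 to 0.10 (ribosomal proteins), -0.10 to 0.19 (glycolysis), -0.15 to 0.041 (inner cell mass), -0.17 to 0.20 (mitochondrially encoded), -0.18 to 0.080 (oocyte) and -0.15 to 0.26 (unfolded protein).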

Other observations

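The splits of the libraries for the number of changed genes, the depth test of control 4, the pathway test, and the choice of genes in the next sentence came only after the results were seen. The 35 genes DESeq2 called included, outside the naming rule, Vim, an intermediate filament gene of mesenchymal cells (DESeq2 log2 fold change -1.22, SE 0.27, adjusted p = 0.00600), Anxa1 (-1.39, SE 0.31, adjusted p = 0.00764), the placental alkaline phosphatase relative Alppl2 (-1.37, SE 0.33, adjusted p = 0.0212), the lactate dehydrogenase gene Ldhb (-2.19, SE 0.47, adjusted p = 0.00420), the interferon-inducible gene Ifi27 (-1.98, SE 0.42, adjusted p = 0.00312) and the placental hormone gene Prl3b1 (-4.12, SE 0.97, adjusted p = 0.0162), whose counts were too low for edgeR's filter. Among 242 KEGG pathways annotated in the deposited table, with those of human diseases left out, 0 passed FDR 0.05 in camera with either correlation. The pathways with the smallest p were oxidative phosphorylation, with 123 genes and a median log2 fold change of 0.18 (FDR = 0.110, adjusted p = 0.977 with an estimated correlation), and aminoacyl-tRNA biosynthesis, with 44 genes and a median of 0.21 (FDR = 0.110, adjusted p = 0.977 with an estimated correlation). Pathways close to other lists past camera's threshold had larger values: cell cycle (FDR = 0.624), lysosome (FDR = 0.656), animal autophagy (FDR = 0.528), tight junction (FDR = 0.517) and steroid biosynthesis (FDR = 0.936). Nearer the threshold were pathways of both directions. DNA replication (FDR = 0.158), the citrate cycle (FDR = 0.158) and terpenoid backbone biosynthesis (FDR = 0.190) were upward. Glycosaminoglycan degradation (FDR = 0.155) was downward. Bile secretion, ECM-receptor interaction, steroid hormone biosynthesis, antigen processing and ovarian steroidogenesis were downward too (each FDR = 0.158). Ovarian steroidogenesis had 23 genes and a median log2 fold change of -0.39. Each of these pathways nearer the threshold had an adjusted p of 0.977 with an estimated correlation.

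One pattern is the excess of lower genes at small p, 24 of 25 at p under 0.001. Further giant cell differentiation in the controls, as a cause of the whole pattern, was set against a mural trophectoderm and giant cell list. Its 10 measured genes of 29 had a median log2 fold change of 0.15, with 8 higher and 2 lower. The SE of that median, 0.17, came from resampling the genes, which are not independent replicates. These values gave no sign of that cause for the measured genes as a set. The list is itself drawn from trophectoderm, however, whose genes stood 0.52 above other genes in the agomir pools. Such a rise could hide the cause, so the test does not decide the question. The values also do not cover the members below the filter. Within the list, Pparg went the other way (-2.42, SE 0.71), as did Prl3b1. Scaling between libraries stays open: the share of lower genes was 0.957 or above under 3 other scalings, but upper-quartile and library-size scaling moved the median of all genes down (-0.066 and -0.11), and median of ratios moved it up only from 0.0048 to 0.023, so none was able to lower that share by much. Chance is not excluded, as 3 of the 35 splits of the 8 libraries gave at least as many genes at p under 0.001 (highest other split 30), and 2 of the 35, the real one included, gave as many in a single direction. In the other splits that reached this number, control 2 and agomir 3, which lay apart on the principal components, fell in the same group. The real split has them in different groups. Among the other splits that kept them in different groups, the highest number was 14, a comparison made after seeing the data. At p under 0.05, 9 of the 35 splits gave as many genes as the 789 of the real one (highest other 1522, with both libraries in the same group). Without control 3 there were 40 genes at p under 0.001, 24 lower and 16 higher. A candidate explanation that stays open is carry-over of cumulus or granulosa cells into the control pools. A second granulosa and cumulus list, fixed before its values were seen, had a median of -0.92 over its 10 measured genes of 24, with 8 lower and 2 higher. The SE of this median, again from resampling its genes and not from the spread between pools, was 0.43. Among its members, Hsd3b1 was at 49.5 against 13.5 CPM, Gja1 at 276 against 152 CPM and Sfrp4 at 8.04 against 1.84 CPM. Hsd3b1 and Sfrp4 were highest in control 3 (79.1 and 15.1 CPM), where Gja1 was lowest among controls (162 CPM, against 170 to 189 CPM in agomir libraries 1, 2 and 4), and Runx1 and Nr4a1 had log2 fold changes of 0.071 and 0.14, so not all members moved together. Of these 10 genes, of which those outside the naming rule are mentioned after their values were seen, at least Gja1, Fn1, Timp1 and Runx1 are also known from the embryo itself, zygotes were washed after fertilisation per the protocol, 11 of the 16 genes of the first list were below the filter, and an effect of the agomir on these genes was not separated from carry-over.

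The second pattern is the 8 gene lists past camera's threshold, and chance is not excluded there either, because 6 of the 35 splits gave as many lists and the highest other split gave 13. With a real count of 0 changed genes, each of the 35 splits reaches it by construction, so this comparison decides nothing (highest other split 1). The seed-match difference of -0.018 was reached or passed in size by 24 of the 35 splits, with -0.066 as the largest other.

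The third pattern is the near absence of Y-linked reads from control 4, which had 48 of them. At the mean share of the other 3 controls 3628 would be expected, 75.6 times as many, so low depth is argued against. Over the 8 libraries, the median X-linked expression relative to autosomes (293 and 8372 genes) was lower where the Y-linked sum was higher, with Pearson's r = -0.85 (exact permutation p = 0.00600) and Spearman's rho = -0.86 (exact permutation p = 0.0107), the one relation tested, as a pool with few or no male embryos would give. Without control 4 and agomir 3, the libraries farthest from the median of the Y-linked sum, r was -0.71 (exact permutation p = 0.128). With 6 libraries and a narrower range of the Y-linked sum, this does not show how far the relation rests on those libraries. Embryo sex was not given, and a different sex ratio between pools of 5 embryos remains a hypothesis.

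In the agomir libraries the mitochondrially encoded genes averaged -0.58 and -0.67 in libraries 1 and 2 and 0.51 and 0.46 in libraries 3 and 4 on the log2 scale relative to all 8 libraries, while the controls lay between -0.053 and 0.15. Cytosolic ribosomal protein genes averaged -0.41, -0.22, 0.26 and 0.18 in agomir libraries 1 to 4, and between -0.17 and 0.18 in the controls.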
